A study of Macaca fascicularis with 10 samples.

How the data were processed

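Total RNA of the dorsal raphe nucleus of 10 female cynomolgus macaques was sequenced after ribosomal RNA depletion as stranded libraries with paired reads of 101 cycles, per the labels' protocols. The same protocol text also describes sonicated nuclei and an antibody step, which belongs to a chromatin assay. No such data were analysed here. Reads were aligned with Novoalign, per the submitters' processing notes, with no version given in the sources used here. The authors deposited 1 table of whole-number counts per gene, with a maternal and a paternal column for each daughter, 20 columns in all. The column names give the build macFas5, per the file headers. How alleles were phased, which positions were used and how reads were filtered is not given in the sources used here. A gene without a value had none in either column of that daughter. Each column was matched to its sample by the sample's title.

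Allele counts were taken to hold only reads that tell the parents apart, which could not be checked. Depth ranged from 30090 to 999471 allelic reads per daughter, so precision differs strongly between daughters and is lowest in daughter 1. The total of a gene follows the number of informative positions in each daughter as well as its expression. Over 1108 genes the median SD between daughters was 0.89 for log2 CPM of allelic reads and 0.53 for the log2 ratio of the alleles. For that reason the planned levels of gene lists, correlations of cell type lists and total-count tests were not run on totals, and the tests of variable genes, title prefix and shared parents were run on the balance of the alleles instead. This departs from the tests fixed before the data were examined.

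Parental columns were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit with a robust prior and glmQLFTest), with the daughter as block and the library size summed over both alleles. Genes needed 10 or more allelic reads in 5 or more daughters, which left 2981 of 7229. The Benjamini-Hochberg threshold was 0.05, and DESeq2 1.42.0 was the other tool. Variable genes were sought as residual deviance of that model against its trend, and title prefix as an interaction with the parental column. Tested on simulated data with 2981 genes for the maternal against paternal comparison, the model recovered 75% of 100 genes changed 2-fold and 100% of 100 changed 4-fold, with 7 false calls, and called 0 when no gene was changed. Each changed gene was changed towards the same column in all daughters. Counts were drawn at the fitted dispersion trend, with no variation particular to a gene, so recovery in the real data may be lower. In 2000 simulated genes, the test of shared parents gave a permutation p of 0.643 with no shared component and 5e-05, the smallest it could give, with a component shared in 5 pairs. That component had the same sign in all 5 pairs and 1 strength. Weaker sharing, or sharing whose sign differs between pairs, was not simulated. In 400 simulated genes, the test of co-expression recovered 82.5% of co-expressed genes and called 1.5% of independent ones.

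Shares of single daughters carry 95% Wilson intervals, which cover counting error only. Means over daughters use daughters with 10 or more reads, and shares over X-linked or single-allele genes use 20 or more. Half-sister similarity used log2 ratios with 0.5 added to each count and 10 or more reads, with 100000 permutations of the daughters. Co-expression used CPM of each allele's own total, with permutation p-values, exact under 10 daughters. X-linked medians were set against 10000 random autosomal gene sets of the same size, drawn within bins of read number. Errors of r between 2 daughters come from 500 bootstrap samples of genes, and those of a mean r over pairs from 300. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Chromosomes were taken by symbol from the gene table of the assembly T2T-MFA8v1.1, which is another build than that of the counts, so none of its coordinates is given. It matched 6566 of 7229 symbols and placed 268 on X and 6286 on autosomes.

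The labels give all daughters 1 group. They come from separate animals. Parental sides are given as the columns are labelled. Title prefix was treated as a technical batch. Named genes followed a rule fixed before the data were examined. Up to 4 members of each of 25 fixed lists with the highest mean level were named, with TPH2, SLC6A4, FEV, SLC18A2, TH and XIST, list members past a threshold, up to 10 genes per direction and test past the threshold, and the 10 genes with the highest level. Where fewer than 5 passed, genes with the smallest p were named as not passing. Some genes that the rule names are not reported here. XIST, FEV, Y-linked genes and the astrocyte and cerebellar lists had no row in the table and were not analysed here. Alternatives were other normalisations and read minimums, DESeq2, leaving out each daughter, rank correlation, and permutation within prefix. Those on X-linked and single-allele genes, the random gene sets, those on each allele's own library size, on transfer RNA genes, on exchanged parental columns, and for shared parents on 20 or 50 reads, on autosomal genes outside the imprinted lists, on the size of r and on daughters 2 and 9 as sharing a father were added after seeing the data.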

Results

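RNA of the dorsal raphe nucleus, the main serotonin cell group of the brainstem, was sequenced in 10 female cynomolgus macaques (Macaca fascicularis), each a daughter with a labelled mother and father. The deposited table gives counts for the maternal and the paternal allele of each gene, so the measurement is the balance between the 2 alleles in 1 animal. The labels give 1 group, 1 tissue and no treatment. The design therefore compares the alleles within daughters, and daughters that share a parent with those that do not. Daughters are numbered 1 to 10 in the order of their labels. The table held 7229 genes, of which 453 could be measured in all 10 daughters and 856 in 1 daughter. Allelic reads per daughter ranged from 30090 in daughter 1 to 999471 in daughter 6, with a mean of 552270 ± 305233 (SD, n = 10). Genes with allelic counts ranged from 1753 in daughter 1 to 4816 in daughter 5.

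The reads were divided nearly evenly between the parents in every daughter. The column labelled paternal held 49.9% ± 0.359 (SD, n = 10) of allelic reads, from 49.3% in daughter 10 to 50.4% in daughter 4. The genes with most allelic reads were transfer RNA genes, led by TRNAG-CCC at 96303 ± 8983 CPM of allelic reads (SD, n = 10), then TRNAP-UGG, TRNAV-AAC, TRNAR-UCG, TRNAW-CCA, TRNAL-UAG and TRNAF-GAA. The 12 transfer RNA genes of the table took 32.6% ± 1.14 (SD, n = 10) of the reads. Next came GNAS, the stimulatory G protein alpha subunit, at 15798 CPM in 5 daughters, the glycolytic enzyme gene GAPDH at 11828 in 10, and the lipid carrier APOE at 8543 in 3. Transfer RNA genes have near-identical copies, so their allelic assignment is uncertain. The name of the deposited counts says that redundant genes were summed. A transfer RNA row may therefore hold several copies, and its level is not that of 1 copy. Their paternal share, the percent of a gene's allelic reads in the column labelled paternal, was 50.4% ± 1.0 for TRNAG-CCC and 49.7% ± 0.952 for TRNAP-UGG (SD, n = 10).

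The first comparison asked which genes were expressed more from the allele of 1 parent across daughters. No gene passed. With edgeR's quasi-likelihood test and the animal as block, 0 of 2981 genes differed between the parental columns at a Benjamini-Hochberg adjusted p of 0.05. The test takes a column as the same parent in every daughter. It can miss genes that are unequal in single daughters but on differing sides, as GRB10 and DLK1 were (below). The 0 therefore does not show that parental differences are absent. At an unadjusted p under 0.05 there were 93 genes with edgeR and 62 with DESeq2, which also called 0. Both counts are a smaller share of the 2981 genes than the 0.05 that chance alone would give. They are therefore no sign of a signal, and the p-values may be conservative, which also limits the 0 calls. Genes with the smallest p, none past the threshold, are given by value. On the maternal side, GPR56, an adhesion receptor, had a paternal share of 39.9% ± 6.78 (SD, n = 9), and GGACT 29.6% ± 7.74 (SD, n = 5). NKD1, an inhibitor of Wnt signalling, had 35.9% ± 8.85 (SD, n = 8), the X-linked KAL1 39.6% ± 6.62 (SD, n = 7), and ZNF584 39.2% ± 5.98 (SD, n = 8). On the paternal side, FAM13A had 58.1% ± 8.59 (SD, n = 9), the signalling scaffold MALT1 63.6% ± 11.5 (SD, n = 5), CPQ 58.8% ± 5.37 (SD, n = 6) and USP53 55.1% ± 5.22 (SD, n = 10). Their adjusted p by edgeR was 1 in each case. Without the read filter 2 genes passed, FAM199X and ZIM2, and without daughter 4 there was 1, the X-linked TSPAN7.

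Some imprinted genes, which are expressed from 1 parental copy, were strongly unequal in single daughters, on sides that differed between daughters. Of 53 measurements of imprinted list genes with 10 or more reads in a daughter, 14 lay beyond 90% on 1 side, all of them in GRB10, DLK1 and MEST, and 17 lay between 40% and 60%. GRB10, a growth factor receptor adaptor, had 96.5% of 311 reads in the paternal column in daughter 3 (95% Wilson interval 93.8 to 98.0), 97.7% of 265 in daughter 4, 96.0% of 225 in daughter 5 and 98.2% of 164 in daughter 10. In daughter 2 it had 5.08% of 315 reads there (3.15 to 8.09), in daughter 6 2.97% of 370 and in daughter 9 9.16% of 251. DLK1, a Notch ligand homologue, took the same side as GRB10 in the 5 daughters with a count of 20 or more, with 98.6% in daughter 3, 100% in daughters 4 and 5, 96.8% in daughter 10 and 1.74% of 115 reads in daughter 6. MEST had 91.3% of 149 reads in daughter 3 and 3.09% of 162 in daughter 6. COPG2, a coat protein gene, lay on the opposite side, with 22.4% in daughter 3 and 23.5% in daughter 5, against 77.6% in daughter 2, 86.3% in daughter 6, 76.1% in daughter 7, 78.0% in daughter 8 and 87.8% in daughter 9. GNAS was less unequal, with 39.2% of 577 reads in daughter 1, 43.6% of 4105 in daughter 4 and 44.2% of 3421 in daughter 5, against 58.4% in daughters 7 and 8. The fixed lists give DLK1 and MEST as expressed from the paternal allele, and GRB10, COPG2 and GNAS as tissue dependent. DLK1 lay on its listed side in daughters 3, 4, 5 and 10, and MEST in daughter 3. In daughter 6 both lay on the other side. Intervals cover counting error only, since reads are not independent molecules.

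**Figure D1:**
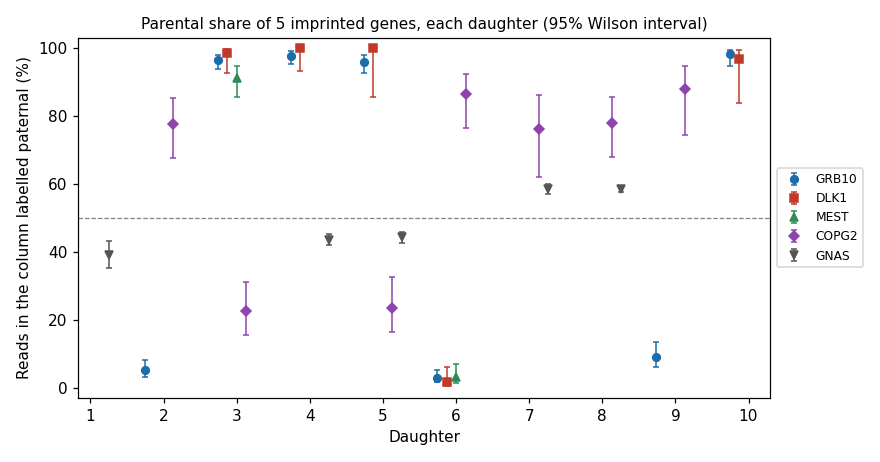
Percent of a gene's allelic reads in the column labelled paternal (vertical axis) for 5 imprinted genes in each daughter (horizontal axis) with 20 or more reads, with 95% Wilson intervals for counting error. GRB10 and DLK1 sit above 90% in daughters 3, 4, 5 and 10 and GRB10 sits below 10% in daughters 2, 6 and 9, while COPG2 sits on the other side of 50% from GRB10.

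The imprinted lists gave no call. Of the 42 imprinted genes fixed before the data were examined, 11 were in the table and 8 were tested, with 0 called over all genes and 0 adjusted over the list alone, by edgeR. The mean paternal share was 57.9% ± 48.9 for GRB10 (SD, n = 7), 79.4% ± 43.4 for DLK1 (SD, n = 5), 64.5% ± 28.7 for COPG2 (SD, n = 7) and 48.8% ± 9.04 for GNAS (SD, n = 5). These means take the columns as labelled, while GRB10, DLK1 or COPG2 lay on opposite sides in daughters 2, 6, 7, 8 and 9 and in daughters 3, 4, 5 and 10. INPP5F, a phosphatase, had 61.4% ± 15.9 (SD, n = 5), with 86.2% of 29 reads in daughter 1 and 47.1% to 66.7% in the others. L3MBTL1 had 54.8% ± 19.7 (SD, n = 9). It took the side of GRB10 in daughters 2, 4, 5 and 10, with 28% of 25, 74.3% of 35, 70% of 90 and 73.7% of 38 reads. It did not in daughters 3, 6 and 9, with 47.5% of 40, 58.7% of 75 and 75% of 16 reads. The Wilson intervals in daughters 3 and 6 include equal shares (32.9 to 62.5 and 47.4 to 69.1). In daughters 7 and 8, where GRB10 had no count, L3MBTL1 lay opposite COPG2, at 35.7% of 14 and 30.4% of 23 reads. Its intervals there include equal shares too (16.3 to 61.2 and 15.6 to 50.9). ATP10A had 52.5% ± 8.77 (SD, n = 8) and TP73 51.9% ± 10.5 (SD, n = 5). ZIM2, outside the lists and named after its values were seen, had 99.8% of 1233 reads in the paternal column in daughter 4 and 99.7% of 2763 in daughter 5.

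Of 21 measurements of serotonin neuron genes with 10 or more reads in a daughter, 16 lay between 40% and 60% paternal and 1 lay beyond 90% on 1 side. All 16 were of TPH2, DDC, SLC18A2 and SLC6A4. The measurements of other list members all lay outside that range and included the 1 beyond 90%, so the balance holds for the named genes and not for the whole list. TPH2, the rate-limiting enzyme of brain serotonin synthesis, had a paternal share of 49.5% ± 3.55 (SD, n = 7). DDC, which makes serotonin and dopamine from their precursors, had 54.6% ± 4.30 (SD, n = 5). The vesicle transporter SLC18A2 had 54.0% ± 2.63 (SD, n = 3) and the serotonin transporter SLC6A4 50.5% and 57.9% in 2 daughters. FEV was not analysed here. TH, the dopamine and noradrenaline synthesis enzyme, had 53.7% ± 10.2 (SD, n = 6). Of the 50 members of the 6 neuronal lists, 23 were in the table and 10 were tested, with 0 called over all genes and 0 adjusted over the list alone. Genes of GABA neurons lay close to balance, with GAD1 at 49.3% ± 3.98 and GAD2 at 50.3% ± 5.80 (SD, n = 6 each). The glutamate transporter SLC17A8 had 48.1% ± 7.95 (SD, n = 9) and the synaptic gene SNAP25 49.1% ± 11.3 (SD, n = 7). The acetylcholine enzyme CHAT had 50.3% ± 10.4 and the choline transporter SLC5A7 44.0% ± 24.3 (SD, n = 6 each). The neuropeptide gene TAC1, precursor of substance P, ranged from 27.4% to 73.5% with a mean of 47.0% ± 13.96 (SD, n = 9).

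Of the 58 members of the lists for glia, vessels, blood and other cells, 15 were in the table and 8 were tested, with 0 called over all genes and 0 adjusted over the list alone. These 8 were endothelial, oligodendrocyte precursor and choroid plexus genes. No astrocyte, oligodendrocyte, microglia, blood or cerebellar gene was tested. PDGFRA, a marker of oligodendrocyte precursors, had 51.4% ± 8.20 (SD, n = 7) and GPR17 49.0% ± 23.0 (SD, n = 9). The endothelial genes VWF and FLT1 had 52.7% ± 11.8 (SD, n = 10) and 47.4% ± 5.13 (SD, n = 8). TTR, a thyroid hormone carrier made by choroid plexus, had 42.6% ± 11.6 (SD, n = 6). The chaperones HSPA8 and HSP90AA1 had 49.1% ± 4.52 and 51.7% ± 7.70 (SD, n = 9 each), and the interferon-induced MX1 54.0% ± 10.5 (SD, n = 8). Among 21 genes linked to neurodevelopmental and psychiatric risk, 9 were tested and 0 passed, over all genes or adjusted over the list alone. ANK3 had 50.9% ± 5.25 (SD, n = 10), SCN2A 49.2% ± 4.40 (SD, n = 6), CNTNAP2 46.9% ± 5.36 (SD, n = 10) and TCF4 41.0% ± 21.6 (SD, n = 7).

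X-linked genes were shifted away from balance in most daughters, and autosomal genes were centred on it. Over genes with 20 or more reads, the median paternal share of X-linked genes was 27.7% in daughters 3 and 5, 29.7% in daughter 10, 39.5% in daughter 2, 43.1% in daughter 9 and 44.9% in daughter 6. It was 73.6% in daughter 4, 57.1% in daughter 7 and 52.7% in daughter 8. Daughter 1 gave 35.6% over 3 genes. The autosomal median was 50% in all 10. The X-linked median lay 13.5 ± 8.06 percentage points from balance (SD, n = 10). It was farther from balance than medians of 10000 random autosomal sets of the same size and like read numbers in 9 of 10 daughters (Benjamini-Hochberg adjusted, random sets of genes, which are not independent replicates). In daughter 8 it was not (2.70 points, adjusted p = 0.0916 from random sets), but over genes with 50 or more reads it was (7.14 points, adjusted p = 0.00112), and daughter 1, with 3 genes, is too thin to weigh (adjusted p = 0.0324). In daughters 3, 4, 5 and 10 it lay over 20 points away, where no random set lay beyond 5.10. Over pooled X-linked reads, 28.8% of 8343 were paternal in daughter 3 (95% Wilson interval 27.8 to 29.7) and 72.8% of 11287 in daughter 4 (72.0 to 73.6). Within title prefix 10203 the distance was 16.4 ± 7.59 points (SD, n = 6) and within 10480 9.26 ± 7.65 (SD, n = 4). TSPAN7, an X-linked membrane protein gene, had 75.8% in daughter 4 and between 29.5% and 41.0% in the other 6 daughters measured.

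**Figure D2:**
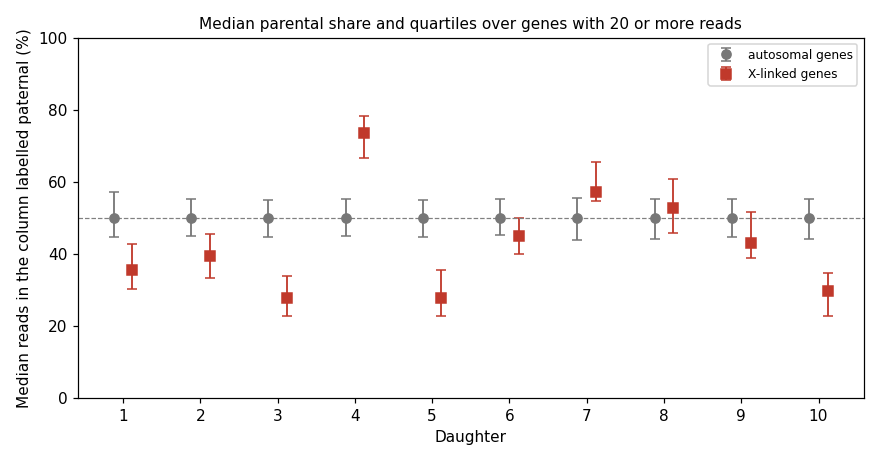
Median percent of allelic reads in the column labelled paternal (vertical axis) over X-linked genes (squares) and autosomal genes (circles) with 20 or more reads, in each daughter (horizontal axis), with quartiles over genes as bars. The autosomal medians lie at 50% and the X-linked medians between 27.7% and 73.6%.

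A small set of genes was read almost wholly from 1 allele. Among 22693 measurements of a gene in a daughter with 20 or more reads, 364 (1.60%) had 90% or more of reads on 1 allele, 182 on each parental side. Binomial counting around equal alleles would give 0.353. These covered 319 of 5243 genes, and 31 genes were in this state in more than 1 daughter, 16 of them on different sides in different daughters. GRB10 was so in 7 of 7 daughters and DLK1 in 5 of 5. CFL1, which encodes the actin regulator cofilin, was so in 4 of 5, the X-linked FAM199X in 4 of 4 and the ribosomal gene RPL38 in 3 of 8. These 3 were named after their values were seen. The share per daughter was 1.74% ± 0.699 (SD, n = 10). A position called as differing between parents in error gives the same appearance, which limits these counts.

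Daughters were then compared for genes whose allelic balance varied more than that of genes with like counts. The test of residual variation against edgeR's trend called 0 of 2981 genes, with 211 at an unadjusted p under 0.05. No other tool was run for it. GRB10 had the smallest p, followed by DLK1 and ITM2C among others, none past the threshold. The test was not tried on simulated data. It did not call GRB10, which ranged from 2.97% to 98.2% paternal, so 0 calls do not show that balance was alike between daughters. GAPDH ranged from 31.04% to 64.8% over the 10 daughters.

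The title prefixes 10203 (6 daughters) and 10480 (4 daughters) were treated as a technical batch. Their parental differences differed for 1 of 2981 genes, CDIPT, a phosphatidylinositol synthase, with a difference of log2 -8.44 ± 0.85 (SE, edgeR adjusted p = 0.0429). The interaction sets 1 daughter of prefix 10480, the only 1 of it with reads, against those of 10203, so it has no replicate in that arm. That is daughter 10, with 0 of 127 reads in the paternal column, against 46.1% to 50.8% in the 3 daughters of prefix 10203 with 20 or more reads. DESeq2 called 0, with 71 genes at an unadjusted p under 0.05, a smaller share of the 2981 than the 0.05 that chance alone would give.

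No difference was detected in the signed correlation of allelic ratios between daughters sharing a parent and other daughters. The mean correlation of log2 paternal over maternal ratios across genes was -0.0035 over the 5 pairs sharing a parent and -0.0034 over the other 40 pairs (permutation test, two-sided, 100000 permutations, p = 0.994; 0.994 when permuted within title prefix). Genes are not independent replicates. Pairs sharing a parent went both ways. In size, regardless of sign, their mean r over autosomal genes outside the imprinted lists was 0.0839, against 0.0424 in other pairs (permutation p = 0.0540, a test added after seeing the data). Over autosomal genes outside the imprinted lists, a set chosen after seeing the data, daughters 4 and 5, with the same father, had r = 0.117 ± 0.0309 (bootstrap SE over 2680 genes), and daughters 7 and 8, also with the same father, 0.105 ± 0.0453. Daughters 6 and 10, with the same mother, had r = -0.0997 ± 0.0265. Daughter 1 had -0.0711 ± 0.0762 with daughter 7 and -0.0265 ± 0.0487 with daughter 8, her labelled paternal sisters (bootstrap SE over 337 and 347 genes). Both lay within 1 SE of 0 and so give no sign. Among the 45 pairs the highest r was 0.230 ± 0.0652, for daughters 2 and 9, which share no labelled parent. Their father labels differ in the first part and are alike in the last, and whether they name 1 animal is not given in the sources used here.

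**Figure D3:**
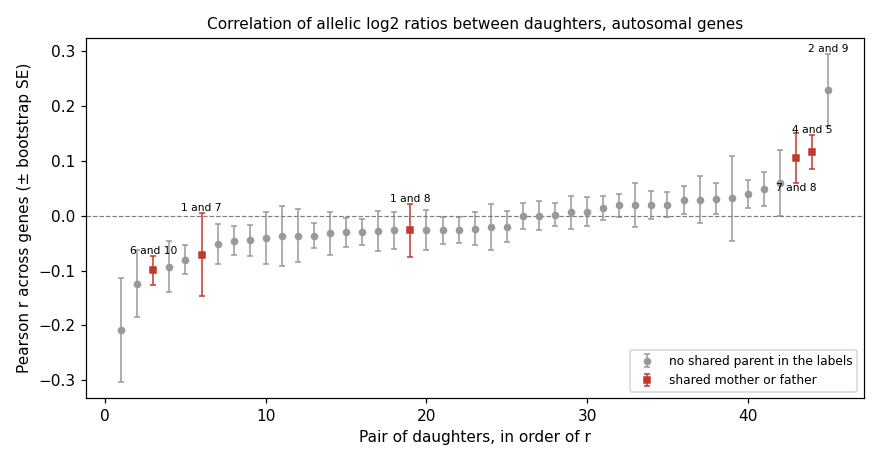
Pearson r across autosomal genes outside the imprinted lists of log2 allelic ratios (vertical axis, bars are bootstrap SE) for each of the 45 pairs of daughters in order of r (horizontal axis), with pairs sharing a labelled parent as squares. These 5 pairs span -0.0997 to 0.117, and daughters 2 and 9 lie highest at 0.230.

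Lastly, the alleles of a gene were compared across daughters. Maternal and paternal CPM rose and fell together for most genes. Among 1108 genes with 10 or more reads in 8 or more daughters, Pearson's r was above 0 in 1083 and below 0 in 25, with a median of 0.858 and a median Spearman's rho of 0.810. Permutation tests with Benjamini-Hochberg adjustment called 822 genes with r above 0 and 0 below. Among 100 permutations of the daughters shared by all genes, at most 797 genes had r above 0 and the highest median r was 0.266. Without the 2 daughters farthest from the median maternal value the median r was 0.773, with 1036 genes above 0. Within title prefix 10203 it was 0.905 over 222 genes. NIF3L1 had the lowest r, -0.69, with an adjusted permutation p of 0.0645. The number of informative positions in a gene differs between daughters and enters both alleles alike, so these r do not measure shared regulation alone.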

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

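The tests of shared parents after an exchange of columns, both tests of agreement between imprinted genes, the tests of reversed imprinting and of autosomal genes after the exchange, and both tests on X-linked genes were chosen after their results were seen. The others were written down before. An outlying daughter was sought in 49 measures, over daughters with 20 or more reads for a gene, and found 10 times, and chance gives about 1 in 20. Some measures, such as FAM199X, were of genes named after their values were seen. The 10 can therefore not be set against that rate. The rule takes no account of counting error.

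GRB10, DLK1, MEST and COPG2, though not every imprinted gene measured, took opposite parental columns in different daughters, and DLK1 in daughter 6 was far from the others at 1.74% paternal, against 96.8% to 100%. Independent differences at each gene stay open. GRB10, DLK1, MEST and COPG2 matched in 19 of 19 shared values (a share of 0.00182 of random signs), but they were picked for the pattern and MEST lies beside COPG2. Over 8 measured list members without MEST the share was 0.129. That set also counts the side of values near balance, such as ATP10A at 50.5% of 99 reads in daughter 3. Neither share can decide the question. Parental columns exchanged in daughters 2, 6, 7, 8 and 9, of which 7 and 8 rest on COPG2 alone, may also account for it, and would give the 3 half-sister pairs with both sides determined a mean r of 0.107 ± 0.0198 (bootstrap SE), but 12.5% of orientations reach that value, so the 95% bound set could not be met. The prediction written beforehand was more calls outside the 4 genes than in any of 99 random orientations. It was not met, with 1 gene, GNAS, against a highest of 2. Those 2, TSPAN7 and HEPH, are X-linked. Over autosomal genes, looked at afterwards, there was 1 call, again GNAS, against a highest of 0. GNAS was measured only in daughters 1, 4 and 5, of title prefix 10203, and in daughters 7 and 8, of prefix 10480. Its call can therefore not tell an exchange from a difference between prefixes. There were also 30 autosomal genes at p below 0.01 against a highest of 24, so the exchange is left undecided. Reversed imprinting would leave half-sisters at r of 0 or above, and the 1 pair that bears on it, daughters 6 and 10, lay below 0 by more than the 2 SE set as the bound (r = -0.0997 ± 0.0265) and lowest of the pairs without daughter 1, but 2 of 33 such pairs with no labelled shared parent passed that bound too (daughters 4 and 10 at -0.0803 ± 0.0261), so it is argued against by 1 pair and not excluded.

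X-linked genes were shifted to 1 side in most daughters, and TSPAN7 in daughter 4 was far from the others at 75.8%. A mapping bias towards 1 parental genome is argued against, since the autosomal median lay 0 percentage points from balance in each daughter. A candidate explanation, unequal X inactivation in the dissected tissue, may account for it, but genes that escape inactivation lay closer to balance in 4 of the 8 daughters where they could be measured, between the bounds of 7 and 3 set for this test. Escape genes lay closer in daughters 2, 3, 4 and 5. In daughters 6, 7 and 9 the other X-linked genes lay at a median of only 6.25, 7.5 and 7.93 points from balance. That left little room for escape genes to lie closer. In daughter 10 escape genes lay farther, at 29.8 points against 20.7. Few escape genes had reads, from 2 to 10 per daughter, which also keeps the explanation open.

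Daughters 2 and 9 had the highest r without a labelled shared parent. Of 32 genes with a log2 ratio beyond 1 in both, 71.9% had the same sign, between the 75% set for an unlabelled shared parent and the 60% set to exclude it. Those bounds separate little, since the 5 pairs with a labelled shared parent gave 25.6% to 70.4%, and pairs without gave up to 69.2% apart from this one. Without genes beyond 1 in either, r was 0.0693 ± 0.0307, but this narrows the ratios that are correlated and also lowered r in daughters 4 and 5 (0.0897) and 7 and 8 (-0.0554), so it does not tell whether a few extreme genes carry the r, and the explanations cannot be told apart. No biological explanation was tested.

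The count of 0 genes between parental columns cannot be set against other orientations of the daughters, since any of them gives as many (100 of 100, highest other 2). For the difference between title prefixes, 24 of 100 splits into 6 and 4 daughters gave 1 gene or more and the highest other gave 6, so chance is not excluded. The difference was CDIPT, at log2 -8.44 in an interaction test with 1 daughter of prefix 10480, daughter 10, which was far from the others at 0% of 127 reads paternal.

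Daughter 1 had fewer genes with counts, 1753, than the others (3181 to 4816). Daughter 7 had a single-allele share of 3.32%, against 1.07% to 2.18%. Among daughters with 20 or more reads of the gene, in daughter 9 SLC17A8 had 29.7% paternal (others 45.2% to 56.8%) and SNAP25 71.2% (others 44.6% to 50.5%). Under the same read limit, TTR had 51.0% in daughter 10 (others 41.3% to 42.7%), CNTNAP2 58.9% in daughter 4 (others 40.8% to 49.8%), and FAM199X 96.3% in daughter 8 (others 98.5% to 98.8%). With fewer reads, TTR had 56.2% and 22.2% in daughters 2 and 3, SNAP25 33.3% in daughter 6 and CNTNAP2 50% in daughter 1.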

How the results depend on the processing

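Alternatives on exchanged columns, each allele's own library size, transfer RNA genes, X-linked and single-allele genes, and for shared parents on 20 or 50 reads, autosomal genes and daughters 2 and 9 were chosen after seeing the data. No paired analysis was possible because there is 1 group; the daughter is already the block between alleles. For genes between parental columns, 0 in the fit reported, there were 2 without the read filter, where more genes were tested, and 0 to 1 leaving out each daughter. With the columns of daughters 2, 6, 7, 8 and 9 exchanged, and daughter 1 as labelled, there were 4, at paternal shares of 95.9% ± 2.47 for GRB10 (SD, n = 7), 98.7% ± 1.35 for DLK1 (SD, n = 5), 20.01% ± 4.89 for COPG2 (SD, n = 7) and 42.0% ± 1.99 for GNAS (SD, n = 5, edgeR adjusted p = 0.0290). The exchange was set by GRB10, DLK1, MEST and COPG2, so their calls are circular, and GNAS was not used to set it. GNAS was measured only in daughters 1, 4 and 5, of title prefix 10203, and in daughters 7 and 8, of prefix 10480. For GNAS the exchange therefore cannot be told apart from a difference between prefixes (log2 0.930 ± 0.132, SE, edgeR adjusted p = 0.223 for that difference). DESeq2, each allele's own library size and leaving out transfer RNA genes gave 0. For title prefixes, 1 in the fit reported, DESeq2 and no read filter each gave 0, and leaving out each daughter gave 0 to 2. CDIPT has enough reads in 5 daughters only, so without daughter 1, 3, 4, 5 or 10 it was not tested, and those fits say nothing of its stability. The cause of its loss with DESeq2 or no read filter was not tested. Variable genes were 0 in every setting run, but that test was not tried on simulated data and did not call GRB10. For shared parents the difference in mean r, near 0 and not past the threshold, changed sign with 20 or more reads (0.0166), centred within title prefix (0.0226) and over autosomal genes outside the imprinted lists (0.0169), none past the threshold (permutation p from 0.565 to 0.812). With daughters 2 and 9 counted as sharing a father, a pair picked for its r, it was 0.0511 (permutation p = 0.131), and 0.0606 over autosomal genes (permutation p = 0.0415). Co-expression with 50 or more reads tested 383 genes, of which 305 were called and 7 had r below 0. The X-linked median stood apart from random sets in 9 daughters, in 8 at 10 or more reads, and in 9 at 50 or more reads and without escape genes. The daughters differed: daughter 8 did not pass in the fit reported (2.70 points) and passed at 50 or more reads (7.14 points), where daughter 1 did not (adjusted p = 0.0922). In all 4 settings daughters 2, 3, 4, 5, 6, 7, 9 and 10 passed, and the single-allele share was 1.29% to 1.87%. With the columns as labelled, of 576 alternative log2 ratios of 44 named genes, 1 crossed the threshold, TSPAN7 without daughter 4 (log2 -0.89, adjusted p = 0.0410). Not run were the alternatives for list levels and cell type correlations, which were not computed. DESeq2 size factors for shared parents were not run, since 1 factor per column leaves r as it is. Depth limits daughter 1 most, with 229 genes of 20 or more reads.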

Other observations

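Imbalance in single daughters was wider than the comparison across daughters shows. By a binomial test per gene with Benjamini-Hochberg adjustment, 9.62% ± 2.30 of genes with 20 or more reads (SD, n = 10) departed from equal alleles, from 5.24% in daughter 1 to 12.3% in daughter 6. These counts cover counting error only and rise with depth. Of 411 such genes in daughter 5, 174 lay below 30% or above 70%.

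Genes that escape X inactivation varied widely. KDM5C, a histone demethylase, had 50.5% paternal of 505 reads in daughter 6, 41.8% of 194 in daughter 3 and 66.7% of 117 in daughter 4. KDM6A had 54.8% of 272 reads in daughter 4 and 35.4% of 271 in daughter 3, but 97.7% of 88 in daughter 6 and 2.17% of 46 in daughter 10. ZFX had 98.5% of 66 reads in daughter 9 and 1.52% of 66 in daughter 10. The list of escape genes was written before they were tested.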
